A study of Homo sapiens with 8 samples.

How the data were processed

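RNA was measured in EndoC-betaH2, a conditionally immortalized human pancreatic beta cell line, here in its proliferating state. Cells had spent 3 days in 5.5, 20 or 35 mM glucose. The 5.5 mM group held 3 libraries, the 20 mM group 2 libraries (replicates 1 and 3) and the 35 mM group 3 libraries. Per the labels' protocols, RNA was taken with a column kit, and stranded libraries were built from polyadenylated RNA. No osmotic control was among the samples analysed here.

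The authors deposited a single table of 28502 transcript rows covering 17300 genes. Per the file headers, it holds read counts per transcript for each of the 8 libraries, not normalized. Per the file headers, it also holds a quantile-normalized log2 value for each library. The deposited table carries the authors' own edgeR comparisons of 20 and 35 mM with 5.5 mM too, as a log2 fold change, a p-value and an adjusted p-value. The submitters' processing notes name the hg19 genome build and edgeR. The aligner, the counting program, the use of strand in counting and all versions are not given in the sources used here. Isoform rows of a gene repeat nearly the same reads, so 1 row per gene was used, the row the authors had marked as best. How that row was chosen is not given in the sources used here. The authors' adjusted p-values ran over all transcript rows. Every per-library column of the deposited table belonged to a sample of the series.

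Counts summed over those transcripts gave 16068205 to 19092537 reads per library. Genes were filtered with filterByExpr, which left 13860 genes, and scaled with TMM factors. All 8 libraries entered a single edgeR quasi-likelihood fit with group means only (edgeR 4.0.16 in R 4.3.3), and the 3 pairwise contrasts were tested with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for genes come from this test unless another tool is named. Levels are TMM-scaled CPM with the SD over libraries, and confidence intervals cover 95%. A linear term in glucose concentration was tested in the same way. P-values measure the spread between these libraries, which the labels do not tie to separate cultures and which may be technical.

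Before the data were examined, 30 gene lists and the rule for naming genes were fixed for beta cell function, nutrient and stress responses, metabolism, growth and other cell types. The 28 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Each was tested again with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from these few libraries, so it can lose a call even where the correlation is small. A call lost this way is therefore not evidence of no change. The text names, for each comparison, up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM and groups that did not overlap. It further names up to 4 members per list with the smallest adjusted p, and 15 genes fixed in advance, of which 1 is not reported here, as is 1 list member. Older symbols in the table were matched to current ones by RefSeq accession for 16806 genes (97.1%) with a RefSeq table for assembly GRCh38.p14. As that is another build than hg19, no coordinates are given.

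Alternatives listed at the same time were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), no filter and a stricter filter on low counts, the replicate number as a block, each library left out, only the groups compared, other thresholds, and the other gene set tests. Chosen after seeing the data, a correction for GC content and transcript length was added. It fitted a smooth trend on GC and on log2 length in each library (mgcv 1.9.3) and entered it as offsets, without carrying the error of that fit. GC and length came from GENCODE transcripts and were found for 13233 of the 13860 tested genes (95.5%). Further additions were fits without the 2 libraries that stood apart from their groups, edgeR's likelihood ratio test, its robust quasi-likelihood test, the row with the most reads per gene, and limma on the deposited log2 values.

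The fits were tested on simulated data with the real means, library sizes and spread and with 200 changed genes, all drawn from those above 5 CPM. At 35 against 5.5 mM, in a fit of 13860 genes, 80.6% of genes changed by 2-fold and 23.9% of those changed by 1.5-fold were recovered. Recovery of genes under 5 CPM was not measured. At 20 against 5.5 mM these shares were 55.2% and 14.9%. Each gene was drawn independently with no library-wide trend, so these shares do not give the recovery in the real libraries. With a GC trend of varying strength added to the simulated libraries, the share recovered at 2-fold fell to 41.8% at 35 mM, and it was 72.3% after the correction over 13233 genes. That trend had no length part, and the changed genes were drawn without regard to GC content. The 72.3% therefore does not show what the correction does in the real libraries.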

Results

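The series examined the expression program of a human beta cell line held in glucose concentrations that stood for normal, high and extremely high blood glucose. EndoC-betaH2 cells, in their proliferating state, were kept for 3 days in 5.5 mM (n = 3 libraries), 20 mM (n = 2) or 35 mM glucose (n = 3). Between 16068205 and 19092537 reads per library were counted with 1 transcript per gene, and 13860 genes were tested. Chromogranin A (CHGA), a core protein of secretory granules, was among the most abundant transcripts and took 2.85% to 5.14% of the reads of a library.

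Libraries of a group did not always lie together. The first principal component of log2 CPM held 57.6% of the variance. Replicate 2 of the 5.5 mM group sat at -57.1 on it and the other 5.5 mM libraries at -22.0 and -13.3. Replicate 1 of the 20 mM group sat at 50.7 and replicate 3 at -17.9, among the 5.5 mM libraries. The 35 mM libraries lay at 26.1, 23.2 and 10.2. Along this axis short, GC-rich transcripts stood against long, GC-poor ones. The median of the first kind minus that of the second, on the log2 scale relative to all libraries, ran from -1.28 in 5.5 mM replicate 2 to 0.87 in 20 mM replicate 1. Counts differed by more than sampling noise in every pair of libraries of a group (chi-square per degree of freedom 3.89 to 83.5), so no library was a copy of another.

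**Figure D1:**
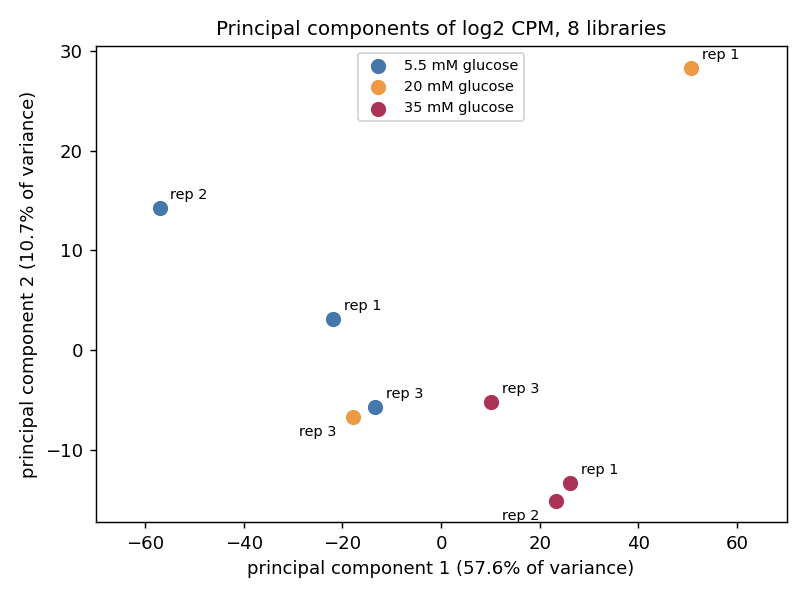
Scores of the 8 libraries on the first and second principal components of log2 CPM (arbitrary units), coloured by glucose concentration, with the replicate number beside each point. On the first component the 20 mM libraries lie at 50.7 and -17.9, on either side of the 35 mM libraries at 10.2 to 26.1.

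The first comparison asked what 20 mM glucose, the hyperglycemic condition, did relative to 5.5 mM. C10orf10 (current symbol DEPP1), a target of FOXO transcription factors, rose 3.93-fold, from 22.0 ± 0.778 CPM (SD, n = 3) to 86.4 ± 12.1 CPM (n = 2). TXNIP, a thioredoxin-binding arrestin long known as a glucose-induced gene of beta cells, rose 4.01-fold from 2.75 ± 0.610 to 11.1 ± 0.804 CPM. C2CD4A, a gene at a type 2 diabetes risk locus, rose 2.77-fold from 8.84 ± 1.32 to 24.5 ± 3.50 CPM. In each of these genes both 20 mM libraries lay above all 3 of the 5.5 mM libraries.

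The log2 fold changes were 1.97 for C10orf10 (95% interval 1.66 to 2.29, adjusted p = 0.000473), 2.01 for TXNIP (1.509 to 2.501, adjusted p = 0.0182) and 1.47 for C2CD4A (1.07 to 1.87, adjusted p = 0.0321). These were the 3 genes past the threshold by edgeR's quasi-likelihood test, and 0 genes fell. At an unadjusted p under 0.05 there were 2333 genes, and DESeq2 called 157. In 3499 genes (25.2%) the groups did not overlap, where chance gives 20%. The authors' deposited table lists 19 genes past 0.05, and these 3 are among them. Leaving out either 20 mM library left 1, which was assumed to vary like the other groups. Without 20 mM replicate 3 that was the library at 50.7 on the first component. The count hung on single libraries. It was 4062 without 20 mM replicate 3, whereas only C10orf10 was left without 20 mM replicate 1, 5.5 mM replicate 1 or 3, or any single 35 mM library, and in a fit of the 20 and 5.5 mM libraries alone. With the correction for GC content and length, chosen after seeing the data, it was 64, these 3 genes included.

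Of the gene lists, 9 were higher at 20 mM than at 5.5 mM and 0 were lower by camera. With an estimated correlation 0 of these calls held. Immediate early and calcium-responsive genes led. Of 19 tested, 17 had a positive log2 fold change, with a median of 0.62 (adjusted p = 2.31e-07; adjusted p = 0.183 with an estimated correlation). Among its members 9 passed when adjusted over the list alone and 0 over all genes. IER3 stood at 10.8 ± 1.69 CPM in 5.5 mM and 23.7 ± 6.59 CPM in 20 mM glucose (adjusted p = 0.242), DUSP1, a phosphatase acting on MAP kinases, at 12.7 ± 1.07 and 21.9 ± 0.888 CPM (adjusted p = 0.242), and the AP-1 subunit JUNB at 17.6 ± 3.71 and 42.8 ± 21.9 CPM (adjusted p = 0.251). Antioxidant genes under NRF2 had a median of 0.48 over 28 members, 8 of them past the threshold when adjusted over the list alone and 0 over all genes (adjusted p = 0.00120; adjusted p = 0.305 with an estimated correlation). SRXN1, which repairs peroxiredoxins, measured 420 ± 14.5 and 653 ± 48.3 CPM (adjusted p = 0.242).

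Chaperones and degradation factors of the endoplasmic reticulum were positive in 24 of 27 members (median log2 fold change 0.21, adjusted p = 0.00565; adjusted p = 0.198 with an estimated correlation), and 3 passed when adjusted over the list alone, against 0 over all genes. WFS1, the gene of Wolfram syndrome, measured 278 ± 25.6 and 388 ± 26.5 CPM (adjusted p = 0.251), while the main chaperone HSPA5 measured 1396 ± 150 and 1452 ± 132 CPM (adjusted p = 0.823). Nuclear-encoded subunits of oxidative phosphorylation were positive in 43 of 48 (median 0.42, adjusted p = 1.19e-05; adjusted p = 0.694 with an estimated correlation). Cytosolic ribosomal proteins were positive in 74 of 81 (median 0.30, adjusted p = 0.000531; adjusted p = 0.708 with an estimated correlation). In both of these lists 0 members passed, over all genes or adjusted over the list alone. Both followed the library that stood apart: relative to all libraries, the mean log2 level of the oxidative phosphorylation genes was 0.48 in 20 mM replicate 1 and -0.24 in replicate 3, and that of ribosomal proteins 0.49 and -0.34. Without 20 mM replicate 1, ribosomal proteins were lower than at 5.5 mM (adjusted p = 0.0006099) and oxidative phosphorylation was no longer called (adjusted p = 0.841, direction down). Without 5.5 mM replicate 2 the call of ribosomal proteins was lost too (adjusted p = 0.242).

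Markers of other islet endocrine cells were also higher at 20 mM (11 of 13 positive, median 0.50, adjusted p = 0.0149; adjusted p = 0.305 with an estimated correlation). SST, the somatostatin gene, at 161 ± 35.7 and 449 ± 226 CPM (adjusted p = 0.242), was the 1 member past the threshold when adjusted over the list alone, against 0 over all genes. The integrated stress response (21 of 31 positive, median 0.18, adjusted p = 0.0253; adjusted p = 0.520 with an estimated correlation), glycolysis (18 of 21, median 0.14, adjusted p = 0.0256; adjusted p = 0.694 with an estimated correlation) and autophagy and lysosome genes (17 of 24, median 0.14, adjusted p = 0.0263; adjusted p = 0.629 with an estimated correlation) were higher as well. Adjusted over the list alone they had 3, 0 and 1 members past the threshold, and over all genes 0. The calls for other islet cells, the integrated stress response, glycolysis and autophagy were lost without 20 mM replicate 1 (adjusted p = 0.0592, 0.0959, 0.513 and 0.357). Without 20 mM replicate 3 those for other islet cells, the integrated stress response and endoplasmic reticulum chaperones were lost (0.0510, 0.0510 and 0.0511), and without 5.5 mM replicate 2 that for glycolysis (0.125). The GC and length correction ended the calls for glycolysis (adjusted p = 0.320), autophagy (0.208) and ribosomal proteins (0.712, direction down). It brought calls for lower cell cycle genes (adjusted p = 0.00222; adjusted p = 0.276 with an estimated correlation) and higher endocrine progenitor and disallowed genes (adjusted p = 0.0472; adjusted p = 0.231 with an estimated correlation). Of the 19 lists without a call at 20 mM, cell cycle genes and endocrine progenitor and disallowed genes had the lowest adjusted p (0.0683 for each) and cholesterol synthesis the highest (0.895).

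The second comparison asked what 35 mM glucose, the extreme condition, did relative to 5.5 mM. The same 3 genes rose and no other gene passed. C10orf10 rose 3.997-fold to 87.9 ± 6.97 CPM (n = 3, log2 fold change 2.00, interval 1.70 to 2.29, adjusted p = 0.000206). TXNIP rose 3.74-fold to 10.3 ± 0.522 CPM (log2 fold change 1.90, interval 1.44 to 2.37, adjusted p = 0.0154). C2CD4A rose 2.46-fold to 21.7 ± 1.03 CPM (log2 fold change 1.298, interval 0.93 to 1.67, adjusted p = 0.0481).

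**Figure D2:**
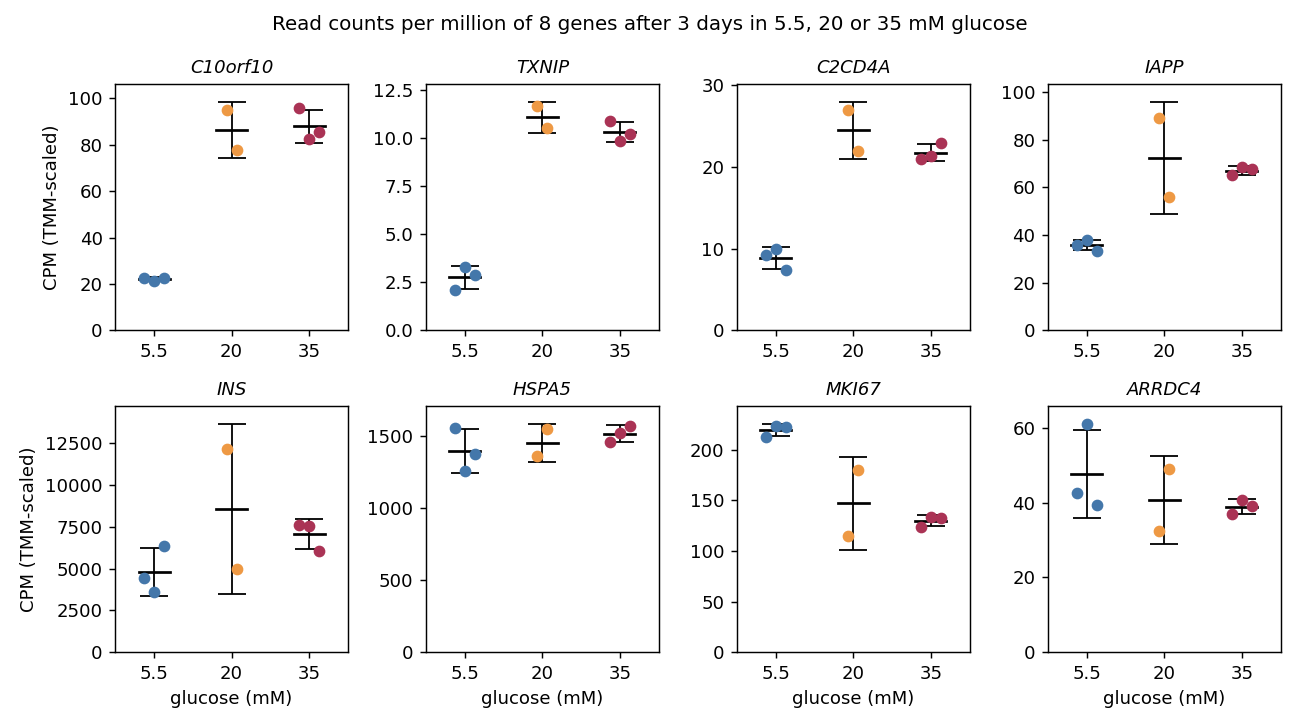
TMM-scaled CPM of 8 genes against glucose concentration in mM, with 1 point per library, a line at the group mean and bars of 1 SD (n = 3, 2 and 3), each axis starting at 0. All libraries at 20 and 35 mM lie above every 5.5 mM library for C10orf10, TXNIP, C2CD4A and IAPP, while INS, HSPA5 and ARRDC4 overlap between 5.5 and 35 mM.

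At 35 mM edgeR's quasi-likelihood test called 3 genes up and 0 down, with 4265 genes at an unadjusted p under 0.05, 1428 called by DESeq2 and 4058 listed in the authors' deposited table. In 6595 genes (47.6%) the groups did not overlap, where chance gives 10%. The number of calls depended on the 20 mM libraries, which share the estimate of the spread: it was 3489 (1710 up and 1779 down) in a fit of the 6 libraries at 5.5 and 35 mM alone, 3442 without 20 mM replicate 1 and 3461 without 20 mM replicate 3, the 3 genes included each time. C10orf10 was the only call left without 5.5 mM replicate 1 or 3 or any 35 mM library. With the GC and length correction the count was 102 (84 up and 18 down), these 3 genes included.

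By camera 8 lists were higher and 0 lower at 35 mM, and 0 calls held with an estimated correlation. Oxidative phosphorylation genes were positive in 45 of 48 (median log2 fold change 0.42, adjusted p = 1.74e-06; adjusted p = 0.609 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. All 3 libraries at 35 mM lay above the 5.5 mM libraries in 38 of them. Over all genes the groups did not overlap, in either direction, in 47.6%. Among the 38 were CYC1 of complex III (114 ± 16.9 and 176 ± 6.27 CPM, adjusted p = 0.116) and COX8A of complex IV (246 ± 48.5 and 415 ± 33.6 CPM, adjusted p = 0.116). In the fit of the 6 libraries with the GC and length correction CYC1 was not called (log2 fold change 0.083, adjusted p = 0.426). COX8A was called there (0.186, adjusted p = 0.0307). Ribosomal proteins were positive in 73 of 81 (median 0.31, adjusted p = 1.16e-05; adjusted p = 0.682 with an estimated correlation), again with 0 members past either threshold. This call ended with the GC and length correction (median 0.03, adjusted p = 0.831), under which oxidative phosphorylation stayed higher (median 0.20, adjusted p = 4.38e-05; adjusted p = 0.616 with an estimated correlation). Many ribosomal protein genes have near-identical pseudogenes, so their reads are uncertain.

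Immediate early genes were positive in 17 of 19 (median 0.51, adjusted p = 2.38e-05; adjusted p = 0.237 with an estimated correlation), and 10 passed when adjusted over the list alone, 0 over all genes. FOS measured 3.93 ± 0.419 CPM at 5.5 mM and 9.16 ± 1.61 CPM at 35 mM (adjusted p = 0.106), and ATF3, shared with the integrated stress response list, 46.2 ± 5.40 and 86.5 ± 1.26 CPM (adjusted p = 0.0569). Of the 28 antioxidant genes 9 were higher and 1 lower when adjusted over the list alone (0 over all genes; median 0.44, adjusted p = 0.00758; adjusted p = 0.522 with an estimated correlation). The glutathione peroxidase GPX2 measured 28.6 ± 5.31 and 65.2 ± 8.39 CPM (adjusted p = 0.116). The 1 lower member was SOD2, the mitochondrial superoxide dismutase (21.5 ± 5.82 and 13.1 ± 2.49 CPM, adjusted p = 0.119). In the fit of the 6 libraries with the GC and length correction SOD2 was not called (log2 fold change -0.12, adjusted p = 0.567). In that fit 11 of the 28 were higher and 0 lower.

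Endoplasmic reticulum chaperones (19 of 27 positive, median 0.23, adjusted p = 0.00965; adjusted p = 0.237 with an estimated correlation) had 3 members past the threshold when adjusted over the list alone. The integrated stress response (22 of 31, median 0.18, adjusted p = 0.0126; adjusted p = 0.609 with an estimated correlation) had 8, autophagy and lysosome genes (19 of 24, median 0.19, adjusted p = 0.0126; adjusted p = 0.609 with an estimated correlation) had 4, and glycolysis (18 of 21, median 0.19, adjusted p = 0.0150; adjusted p = 0.609 with an estimated correlation) had 3. In each of these lists 0 members passed over all genes. Examples were the translocon subunit SEC61B (169 ± 21.7 and 284 ± 12.9 CPM, adjusted p = 0.116), DDIT3, the CHOP transcription factor (159 ± 26.7 and 250 ± 14.3 CPM, adjusted p = 0.116), the autophagy receptor SQSTM1 (648 ± 56.6 and 1069 ± 36.7 CPM, adjusted p = 0.109) and the aldolase ALDOA (628 ± 127 and 1014 ± 68.7 CPM, adjusted p = 0.116). The calls for glycolysis and autophagy were lost with the GC and length correction (adjusted p = 0.318 and 0.107), and glycolysis also without 5.5 mM replicate 2 (adjusted p = 0.0605).

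**Figure D3:**
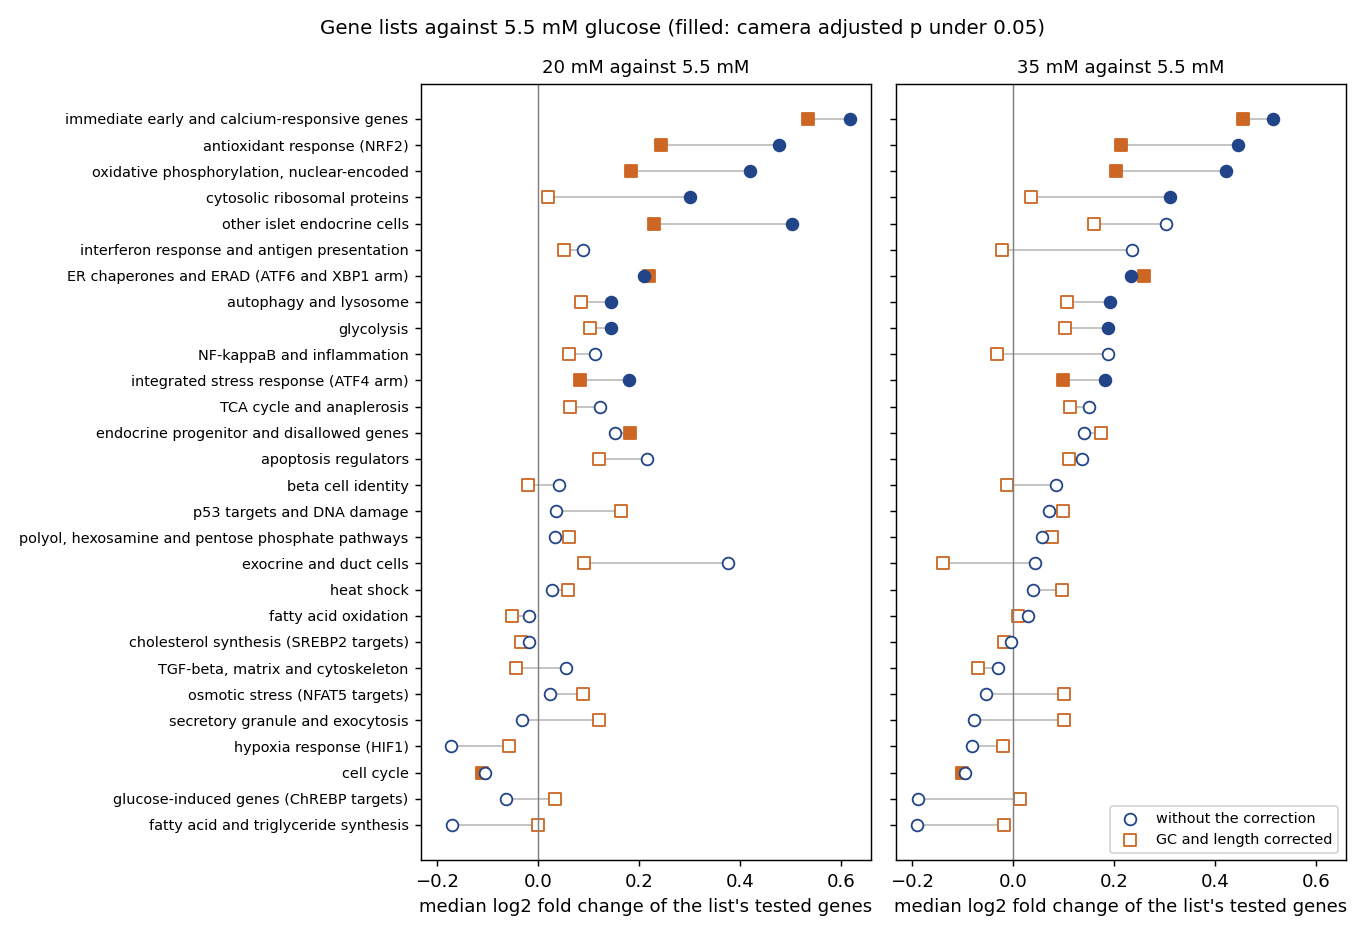
Median log2 fold change of each of the 28 tested gene lists against 5.5 mM glucose, at 20 mM (left) and 35 mM (right), without (circles) and with (squares) the GC and length correction, which was chosen after seeing the data; filled symbols have a camera adjusted p under 0.05. The median of cytosolic ribosomal proteins at 35 mM moves from 0.31 to 0.03, and that of endoplasmic reticulum chaperones from 0.23 to 0.26.

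Genes that define the beta cell showed no call as a group at 35 mM (18 of 32 positive, adjusted p = 0.412) or 20 mM (18 of 32, adjusted p = 0.532). IAPP, the islet amyloid hormone secreted with insulin, measured 35.8 ± 2.27 CPM at 5.5 mM, 72.5 ± 23.5 CPM at 20 mM and 67.1 ± 1.74 CPM at 35 mM, and was the 1 member past the threshold at 35 mM when adjusted over the list alone (adjusted p over all genes = 0.116; 0.00517 with the GC and length correction). INS stood at 4800 ± 1434 CPM, 8579 ± 5078 CPM and 7065 ± 879 CPM (adjusted p = 0.279 at 20 mM and 0.217 at 35 mM). Its reads are shared with the overlapping INS-IGF2, and its log2 fold change at 35 mM moved from 0.56 to -0.19 with the GC and length correction. The transcription factors PDX1 (252 ± 23.6 CPM at 5.5 mM and 299 ± 21.8 CPM at 35 mM) and NKX6-1 (85.0 ± 8.84 and 80.6 ± 4.18 CPM) had adjusted p-values of 0.188 and 0.725. In the fit of the 6 libraries with the GC and length correction NKX6-1 was lower (adjusted p = 0.0217) and PDX1 was not called (0.902). MAFA stayed under 1 CPM in each group mean. SLC2A2, with at most 2 reads in a library, and G6PC2, with at most 12, were too low to test.

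The list of glucose-induced genes, which holds TXNIP, was not called at 35 mM (9 of 19 positive, adjusted p = 0.954) or 20 mM (adjusted p = 0.733). ARRDC4, a close relative of TXNIP, measured 47.7 ± 11.7 CPM at 5.5 mM and 38.9 ± 1.95 CPM at 35 mM (adjusted p = 0.320). RGS16, a regulator of G protein signalling, measured 7.75 ± 1.33 and 16.0 ± 2.21 CPM (adjusted p = 0.116; 0.00209 in the fit of the 6 libraries with the GC and length correction). Over all genes 1 member of the list was called at 35 mM, TXNIP, and adjusted over the list alone 3 were higher and 1 was lower. In the corrected fit of the 6 libraries 3 of 18 were higher and 1 was lower.

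Cell cycle genes were not called at 35 mM (14 of 36 positive, adjusted p = 0.153), although 6 members were lower and 1 higher when adjusted over the list alone, against 0 over all genes. The proliferation marker MKI67 measured 220 ± 5.86 CPM at 5.5 mM and 130 ± 5.61 CPM at 35 mM (adjusted p = 0.116), and the topoisomerase TOP2A 222 ± 51.0 and 116 ± 16.4 CPM (adjusted p = 0.116). Both were called lower in the fit of the 6 libraries (adjusted p = 0.00656 and 0.0129). With the GC and length correction the list was lower at 35 mM (adjusted p = 0.00255; adjusted p = 0.332 with an estimated correlation). The p53 target CDKN1A, which halts the cell cycle, measured 26.6 ± 2.69 and 53.2 ± 4.86 CPM (adjusted p = 0.106; its list, adjusted p = 0.263). Osmotic stress genes were not called (6 of 15 positive, adjusted p = 0.708). Among them the aldose reductase AKR1B1 measured 146 ± 21.7 and 184 ± 6.57 CPM (adjusted p = 0.168) and the inositol transporter SLC5A3 22.5 ± 5.93 and 17.9 ± 2.65 CPM (adjusted p = 0.342). In the fit of the 6 libraries with the GC and length correction 3 of 14 osmotic genes were higher and 0 lower (list camera adjusted p = 0.683). The log2 fold change of SLC5A3 in these libraries moved from -0.33 to 0.29 with the correction (adjusted p = 0.0973).

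The other lists without a call at 35 mM were those of other islet endocrine cells (adjusted p = 0.0813), the tricarboxylic acid cycle (0.153), endocrine progenitor and disallowed genes (0.153), fatty acid and triglyceride synthesis (0.257), interferon response (0.263), apoptosis regulators (0.395), exocrine and duct cells (0.455), heat shock (0.657), polyol, hexosamine and pentose phosphate pathways (0.657), hypoxia (0.669), fatty acid oxidation (0.708), secretory granules and exocytosis (0.708), NF-kappaB (0.708), TGF-beta and matrix (0.826) and cholesterol synthesis (0.945). Of other islet cells, SST measured 161 ± 35.7 CPM at 5.5 mM and 433 ± 44.4 CPM at 35 mM (adjusted p = 0.113), and of the granule genes CHGA measured 31851 ± 5888 and 50549 ± 3591 CPM (adjusted p = 0.116). Of mesenchymal, endothelial and blood cell markers only COL3A1 and CD68 were expressed enough to test. COL3A1 measured 0.318 ± 0.413 CPM at 5.5 mM and 0.490 ± 0.209 CPM at 35 mM (adjusted p = 0.604), and CD68 15.7 ± 1.07 and 12.3 ± 1.69 CPM (adjusted p = 0.176; 0.0101 in the fit of the 6 libraries with the GC and length correction). Mitochondrially encoded genes were not analysed here.

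The third comparison set 35 mM against 20 mM, the extreme against the high condition. C10orf10 differed by 0.03 on the log2 scale (interval -0.29 to 0.34), TXNIP by -0.10 (-0.58 to 0.37) and C2CD4A by -0.17 (-0.57 to 0.23). By edgeR's quasi-likelihood test 0 genes passed, with 140 at an unadjusted p under 0.05, where 693 are given by chance, and DESeq2 called 0. By camera 0 lists passed. The lowest adjusted p was 0.563, for ribosomal proteins and for osmotic stress genes. The 20 mM group had 2 libraries that lay far apart. Without both 5.5 mM replicate 2 and 20 mM replicate 1, a fit chosen after seeing the data that leaves 1 library at 20 mM, 2255 genes passed. Leaving out 20 mM replicate 1 or 20 mM replicate 3 alone gave 0 genes and 2 lists each, higher in the former case and lower in the latter.

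C10orf10, TXNIP and C2CD4A were called in both comparisons with 5.5 mM, where independent lists would share 0.000649 genes. In 50 simulations of unchanged groups against the shared 5.5 mM libraries 0 genes were called in both. These drew each gene independently with no library-wide trend, so they cannot show how much overlap such a trend would make. As those 3 control libraries cannot be split into groups of at least 2, part of the overlap may come from them. Leaving out a 20 mM library left 1 at 20 mM, assumed to vary like the other groups. The overlap was 2680 genes without 20 mM replicate 3 and 1 gene without 20 mM replicate 1, 5.5 mM replicate 1 or 3, or any 35 mM library. A linear trend with glucose concentration called 0 genes by edgeR's quasi-likelihood test, with 4287 at an unadjusted p under 0.05 and 1326 called by DESeq2. C10orf10, at the same level at 20 and 35 mM, had an adjusted trend p of 0.118. Without 20 mM replicate 1 the trend called 3866 genes.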

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

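The GC and length correction, the fits without both outlying libraries (5.5 mM replicate 2 and 20 mM replicate 1), the likelihood ratio test, the robust test, the row with the most reads and limma on the deposited values were chosen after seeing the data. C10orf10 was past the threshold in both comparisons with 5.5 mM under all 22 alternatives (log2 fold change 1.794 to 2.108 at 20 mM and 1.779 to 2.038 at 35 mM). TXNIP missed it in 9 of 22 at 20 mM and 5 of 22 at 35 mM, and C2CD4A in 10 and 9, always with a rise. Main counts were 3, 3 and 0 genes (20 against 5.5, 35 against 5.5, 35 against 20 mM), 3 in both, 0 for the trend, and 9, 8 and 0 lists. The DESeq2 Wald test called 157 and 1428 genes, 146 in both and 1326 for the trend. No filter gave 6 and 31 genes, 6 in both, and the stricter filter 1 list between 35 and 20 mM. The replicate block gave 1 gene at 20 mM and 2 at 35 mM, with 1 in both and 1 list between 35 and 20 mM. A fit of only the groups compared gave 1 and 3489 genes, 1 in both. An adjusted p under 0.01 left 1 gene in each comparison with 5.5 mM and in both, and 5 lists in each. Camera with an estimated correlation called 0 lists in each comparison, also after the GC and length correction, and fry 5 and 5 against 5.5 mM. Leaving out 1 library at a time gave 1 to 4062 genes at 20 mM, 1 to 3461 at 35 mM, 1 to 2680 in both, 0 to 3866 for the trend, and 0 to 2 lists between 35 and 20 mM. Where 20 mM was left with 1 library, that library was assumed to vary like the other groups. The GC and length correction gave 64 and 102 genes, 56 in both, and with only the groups compared 1 and 2123, 1 in both. Without both outlying libraries there were 38, 3359 and 2255 genes, 27 in both, 2029 for the trend and 3 lists between 35 and 20 mM, and with the correction 528, 2398 and 1393 genes, 291 in both, 1161 for the trend, and 5 lists at 35 mM and 2 between 35 and 20 mM. The likelihood ratio test called 217 and 1365 genes, 176 in both and 1014 for the trend. Limma on the deposited values called 4 lists at 35 mM. Except where fewer libraries or another error model made the difference by construction, the cause was not tested.

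Directions reversed in few results, given as adjusted p for lists. Without both outlying libraries, first without and then with the correction, glycolysis at 20 mM was lower (0.6599 and 0.5441), as were oxidative phosphorylation (0.0001308 and 0.0224) and ribosomal proteins (4.681e-23 and 3.768e-16). Leaving out 1 library at a time, oxidative phosphorylation at 20 mM ranged from 8.57e-11 (without 20 mM replicate 3, higher) to 0.8411 (without 20 mM replicate 1, lower). Ribosomal proteins at 20 mM ranged from 3.382e-12 (without 20 mM replicate 3, higher) to 0.242 (without 5.5 mM replicate 2, higher), with 0.0006099 without 20 mM replicate 1, lower. Ribosomal proteins at 20 mM were also lower with the correction (0.7121, 0.8217 with only the groups compared, and 0.9878 with an estimated correlation), and at 35 mM with the correction and without both outlying libraries (0.2703). The log2 fold change of INS was -0.2073 at 20 mM and -0.1983 at 35 mM in that last fit, -0.1908 at 35 mM with the correction and only the groups compared, and 0.502 between 35 and 20 mM without both outlying libraries. The cause was not tested. In the other values of single genes, 760 kept direction and side of the threshold, 49 came past it, 33 lost it, and 63 changed sign without a call in either fit. For lists 286 kept both and 93 lost the threshold. A pseudocount applied only to normalized values and was not run, and the DESeq2, likelihood ratio and robust tests gave no list values, nor a fit of only 2 groups a trend. Depth set the limit for SLC2A2 and G6PC2, with at most 2 and 12 reads in a library.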

Other observations

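The tests in this part were chosen after the results were seen, except the fit of 6 libraries and the splits of the libraries that were made without the GC and length correction. In the 6 libraries at 5.5 and 35 mM alone, with the GC and length correction, 2123 genes were called by edgeR's quasi-likelihood test (1242 higher and 881 lower at 35 mM). Without the correction 3489 were called, of which 1198 were shared, 1197 of them in the same direction. QSOX1, a disulfide-forming oxidase of the secretory pathway, had 530 CPM at 5.5 mM and 871 CPM at 35 mM (corrected log2 fold change 0.98 ± 0.09 SE, adjusted p = 0.000104 in the 6 libraries). SST (0.98 ± 0.07, adjusted p = 6.38e-06), IAPP (1.03 ± 0.08, adjusted p = 7.51e-06) and the arginase ARG2 (0.95 ± 0.07, adjusted p = 7.51e-06) rose in the same fit. Of all 12886 genes tested in this fit 1242 rose and 881 fell. Of 27 endoplasmic reticulum genes 16 rose and 1 fell (camera adjusted p = 2.92e-05, and 0.1775 with an estimated correlation). HSPA5 was among those that rose (log2 fold change 0.33, adjusted p = 0.0224). Without the correction it was not called in the 6 libraries (0.12, adjusted p = 0.419). Of 48 oxidative phosphorylation genes 17 rose and 0 fell (camera adjusted p = 6.24e-06, and 0.477 with an estimated correlation of 0.42). INS went the other way: its log2 fold change was 0.56 without the correction (adjusted p = 0.0481) and -0.19 with it (adjusted p = 0.0224). In these libraries the GC and length trend ran with glucose. Short, GC-rich transcripts minus long, GC-poor ones stood at -1.28 to -0.11 at 5.5 mM and at 0.19 to 0.55 at 35 mM. The correction may therefore also remove a real change shared by such transcripts, and the direction of INS stays open.

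Some genes that fell in the same corrected fit of 6 libraries are given here, chosen after their values were seen. COL18A1 (log2 fold change -0.79 ± 0.13 SE, adjusted p = 0.00268), COL4A2 (-0.48 ± 0.08, adjusted p = 0.00276) and COL5A1 (-0.996 ± 0.186, adjusted p = 0.00460) and ADAMTS2 (-0.65 ± 0.08, adjusted p = 0.000572) were lower at 35 mM, as was GRIK3 (-0.94 ± 0.09, adjusted p = 0.000111). The fixed list of TGF-beta and matrix genes had 4 members lower and 0 higher of 17 and was not called (adjusted p = 0.101; adjusted p = 0.376 with an estimated correlation). The fixed markers of other cells CD68 (-0.57 ± 0.13, adjusted p = 0.0101) and CPA1 (-0.66 ± 0.16, adjusted p = 0.0140) were lower in this fit too, and of 7 exocrine and duct genes 1 rose and 1 fell (list adjusted p = 0.799; adjusted p = 0.816 with an estimated correlation). A change in the share of other cells was not tested. Of 35 cell cycle genes 8 fell and 0 rose (list adjusted p = 0.00484; adjusted p = 0.392 with an estimated correlation).

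On the main axis of variation, a trend with GC content and transcript length may account for part, since these took 49.7% of the variance of the first component's gene loadings, while glucose alone cannot: the 20 mM libraries lay 68.6 units apart, and the means of 35 and 5.5 mM 50.6. A test on gene lists left open whether 20 mM replicate 3 is a 5.5 mM library with a wrong label. It used the 6 lists called with the preset correlation in the corrected fit of the 6 libraries at 5.5 and 35 mM. In 5 of the 6 lists the library lay past all 5.5 mM libraries, toward 35 mM, and in 3 by more than their range. It lay within that range in oxidative phosphorylation (adjusted p = 0.477 with an estimated correlation). The 3 were endoplasmic reticulum chaperones, antioxidant and immediate early genes (adjusted p = 0.1775 with an estimated correlation for each), the others the integrated stress response and cell cycle genes (adjusted p = 0.392 with an estimated correlation for each), so 0 of the 6 calls held. For the chaperones the estimated correlation was 0.006, under the preset 0.01, so correlation does not explain the loss of their call. This test was chosen after the level of TXNIP and 6 versions of the library's median position between the 5.5 mM mean (0%) and the 35 mM mean (100%) had been seen. Of these versions 1 (3489 called genes, the GC and length trend left in) put it at 29.4%, under the 40.5% of 5.5 mM replicate 3. The other 5 put it at 35.1% to 75.2%, above the 5.5 mM libraries. The test was also chosen after a look at the fit of all libraries, whose number of calls depends on 20 mM replicate 3. C10orf10, TXNIP and C2CD4A were also called at 35 mM in the fit of the 6 libraries, which does not use it. Its log2 level lay above the highest 5.5 mM library by 2.61 (TXNIP), 2.65 (C2CD4A) and 19.3 (C10orf10) times the range of the 5.5 mM libraries. For these 3 genes the levels argue against a 5.5 mM library with a wrong label. So do the 37 genes of the corrected fit of the 6 libraries at a log2 cutoff of 1. In 30 of the 37 it lay past every 5.5 mM library, at a median position of 62.0%. The highest 5.5 mM library stood at 11.5%. Of the 8 lists called in the fit of all libraries, 20 mM replicate 3 lay above the 5.5 mM libraries in 5, by more than their range in 2 (0 of these 8 calls held with an estimated correlation). What set the libraries apart stays open, as RNA quality and library batch are not given in the labels used here.

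Ribosomal proteins and oxidative phosphorylation genes moved with that axis. Their median log2 fold change was used as the measure after its value and the adjusted p had both been seen. After the correction that of ribosomal proteins at 35 mM was 0.0343 (adjusted p = 0.831), against 0.31 before, so the library-wide trend may account for it. That of oxidative phosphorylation genes fell from 0.42 to 0.204, and the list stayed called with the preset correlation (adjusted p = 4.38e-05; adjusted p = 0.616 with an estimated correlation). Whether the trend or a response to glucose made the rest of this difference therefore stays open.

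The rise of C10orf10, TXNIP and C2CD4A at 35 mM was argued against as a product of the GC and length trend: each gene stayed past the threshold, and the smallest share of a log2 fold change kept was 0.891. Glucose may act on them by way of its metabolism or of osmolarity, and the 2 were not separated by these samples (0.891 bears on the GC and length trend alone). Of the 10 splits of the 6 libraries at 5.5 and 35 mM, 1, the real one, gave as many genes: 3 genes, against a highest other count of 0. With the correction the real split gave 102 and the others at most 0, and in the fit of the 6 libraries alone 3489 and at most 0. For lists the real split gave 8 and the highest other 6. With 10 splits the share cannot fall under 0.05. Each other split mixes both concentrations, so any real difference adds to the spread within its groups and lowers its count. The real split also follows the GC and length trend. The counts without the correction therefore cannot tell glucose from that trend.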
